A study of Glycine max with 15 samples.

How the data were processed

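Messenger RNA of soybean seedlings (Glycine max, cultivar Williams 82, 10 days old, first vegetative stage) was sequenced from 15 libraries in 5 groups of 3, prepared with a stranded TruSeq kit per the labels' protocols. Nothing in the labels says whether the 3 libraries of a group came from separate plants or pots, so the p-values measure the spread between those libraries, which may be technical.

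The authors deposited 4 full tables, each comparing 1 treated group with the control over the same 54175 gene IDs, and 4 short lists of gene IDs with a fold change. Cuffdiff made the full tables, per the file headers, whose columns carry that program's names. The version, the aligner, the genome build and the annotation are not given in the sources used here. Expression is in FPKM, which is fragment counts scaled for transcript length and library size, pooled by the authors into 1 value per group and table, so no value per library was analysed here. The scale also depended on the table, since control FPKM differed between tables. The score in the tables is the authors' Cuffdiff test statistic, and the deposited p-value has a smallest possible entry of 5e-05 in each table. The deposited q-value was recovered by Benjamini-Hochberg adjustment over the genes with test status OK, with a largest difference of 5.29e-07. Fold changes were deposited by the authors as the log2 of treated over control FPKM, with an infinite value or a spreadsheet error where a group was listed at 0, and the short lists hold the same log2 values to within 5.09e-05. The depth of the libraries is unknown, since FPKM pooled over libraries keep no read totals, and no interval that needs a depth was computed.

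The sheet names and the column headers of the full tables conflict. The sheet named Pcz has the header Pcz, but the sheet named Pcz-BL has the header Pcz-BL-1h, the sheet named Pcz-BL-1h has the header Pcz-BL-8h, and the sheet named Pcz-BL-8h has the header Pcz-BL. Tables were assigned to groups by sheet name, because the sample labels cite the sheet names and each short list holds the fold changes of the full table with the same sheet name. The size or direction of the changes was not used to decide. Every statement on a treatment other than Pcz alone depends on this choice, so the tables are called by their sheet names throughout.

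A gene was called changed at an authors' q of 0.05 or less with test status OK, and the sign of the authors' fold change gave its direction. The planned fit on values per library, with the replicate number as a block and with each library left out, could not be made on pooled values, and the fallback fixed with it, the authors' own test, was used. A standard error was taken per gene as the absolute ratio of the fold change to the test statistic. Correlations between tables used log2(FPKM + 1), and fold changes on that scale understate the change of genes with low values. Because all tables share the control libraries, unchanged groups with a shared control were simulated in 20 draws from the standard errors, leaving out genes with a standard error above 3. Overlaps were compared with the product of independent lists and by two-sided Fisher's exact tests, 24 in all, with 95% intervals of the odds ratios. Differences between treated groups were taken as ratios of FPKM with no p-value, since the tables were normalised separately. As an addition chosen after the files were examined, a z test compared the fold changes of 2 tables from their standard errors. Tested on simulated data, this test recovered 25%, 46%, 17% and 18% of planted differences of 2 on the log2 scale, and 86%, 91%, 81% and 89% of planted differences of 4, for Pcz-BL, Pcz-BL-1h and Pcz-BL-8h against Pcz and Pcz-BL-8h against Pcz-BL-1h, with 0 false calls. The test takes the errors of the 2 tables as independent although both use the control libraries, which makes it call too few genes. In the simulation the control error was shared and cancelled from the difference, so 0 false calls were favoured by the set-up.

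Genes were binned by mean FPKM over the 5 groups, with control averaged over its 4 columns first. An earlier binning on the mean of all 8 columns counted control 4 times; it was replaced after its results had been seen, and both are given in the results. Neighbouring genes were compared by the order of loci in the tables on 20 chromosomes, with gene calls permuted over positions 1000 times (100 times for runs of genes), and 258 IDs that name a scaffold were left out. Only tested genes were ordered (33601 in Pcz, of 53917 on the chromosomes), so neighbours and runs pass over untested genes. Of the 54175 IDs, 0 matched the gene table of the reference used here (59048 genes, assembly Glycine_max_v4.0), and the files do not pair the IDs with names. The 28 gene lists fixed before the data were examined could therefore not be applied, and no gene is named. In their place, by a rule fixed at the same time, the 2 IDs with the highest and the 2 with the lowest fold change are given per comparison, among called genes with FPKM above 0 in both groups and at least 5 in the higher one. Alternatives covered the q threshold (0.01), a 2-fold minimum, a filter at FPKM of 1, pseudocounts of 0.1 and 5, scaling to a common median, recentring, overlapping gene models, another control column and a p-value from the normal distribution of the test statistic. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.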

Results

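Transcript levels were measured by RNA sequencing in soybean seedlings given propiconazole (Pcz), an inhibitor of brassinosteroid synthesis, with or without brassinolide (BL), the most active brassinosteroid. Brassinosteroids are steroid hormones that promote cell elongation. The 15 libraries formed 5 groups of 3: mock-treated control, 5 mM Pcz, 5 mM Pcz together with 10 nM BL, and 5 mM Pcz followed by 1 mM BL for 1 h or for 8 h, with units as the labels give them. These millimolar doses are high for such compounds and no other source for the unit was at hand, so the doses are uncertain. Among the 5 groups none was given Pcz and then a mock addition for 1 h or 8 h. Differences of the high-BL groups from Pcz, or from each other, can therefore not be told apart from effects of the addition itself or its timing. The tables give 1 pooled FPKM per group, so no spread between replicates can be shown and the authors' test is the measure of significance. Of 54175 gene IDs, 33690, 35343, 36884 and 34619 were tested in the tables named Pcz, Pcz-BL, Pcz-BL-1h and Pcz-BL-8h. By sheet name these hold Pcz alone, Pcz with low BL, high BL for 1 h and high BL for 8 h. By column header the last 3 would hold high BL for 1 h, high BL for 8 h and a group headed Pcz-BL, so the treatment behind each of those 3 tables is open.

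The first comparison asked which genes responded to the inhibitor alone. With Pcz, 17974 of 33690 tested genes (53.4%) differed from control, 8399 higher and 9575 lower. Lower genes moved further than higher ones, with a median log2 fold change of -1.47 against 1.02. Glyma09g31740 (chromosome 9, 38382761 to 38383979) rose from 14.2 to 11557 FPKM in the authors' deposited table (log2 fold change 9.67, q = 0.000970). Its standard error was 2.05, against a median of 0.391 over tested genes, so the size of this rise is uncertain. In the same authors' deposited table Glyma13g35320 (chromosome 13, 36771222 to 36772297) rose from 3.21 to 2303 FPKM (log2 fold change 9.49, q = 0.000188). Glyma07g04310 (chromosome 7, 3163390 to 3164534) fell from 155 to 0.146 FPKM in the authors' deposited table (log2 fold change -10.05, q = 0.00868). A fall from 584 to 0.568 FPKM was listed for Glyma14g14220 (chromosome 14, 13954967 to 13956050) in the authors' deposited table (log2 fold change -10.01, q = 0.000188). With p taken from the normal distribution of the deposited test statistic, 11480 genes were called; with a 2-fold minimum, 11160 were.

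These 4 genes took different courses in the other tables. Glyma14g14220 was also low in the authors' deposited table Pcz-BL (2.67 FPKM), was not called in Pcz-BL-1h (597 FPKM, q = 0.641) and stood above control in Pcz-BL-8h (2908 FPKM). Glyma07g04310 had 2.75, 348 and 1370 FPKM in those 3 tables and was called in each of the authors' deposited tables. Glyma09g31740 was higher than control in the authors' deposited table Pcz-BL (60.2 FPKM) and lower in Pcz-BL-1h (0.384 FPKM) and Pcz-BL-8h (0.142 FPKM). Glyma13g35320 was higher in the authors' deposited table Pcz-BL (152 FPKM), was listed at 0 and called lower in Pcz-BL-1h, and was not called in Pcz-BL-8h (q = 0.244).

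**Figure D1:**
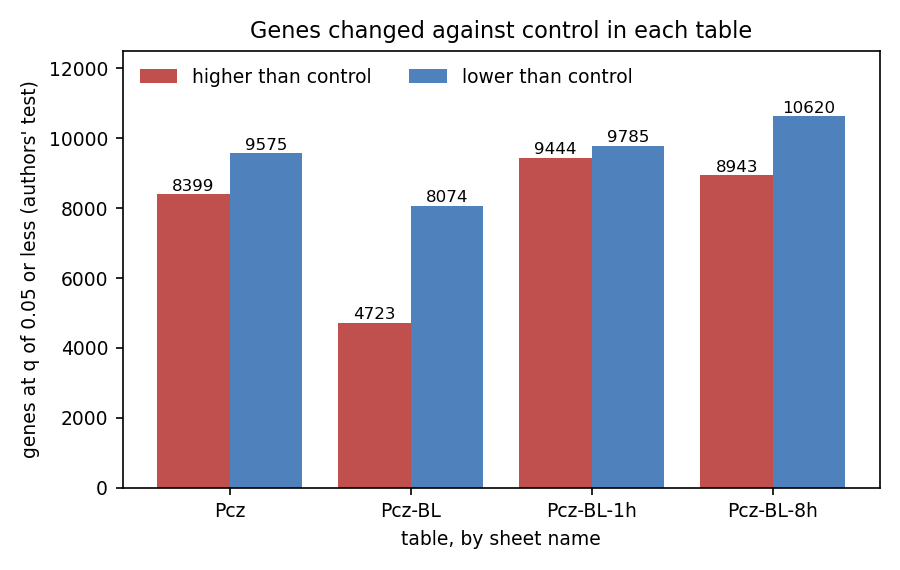
Number of genes (vertical axis) with an authors' q of 0.05 or less in each of the 4 tables (horizontal axis, by sheet name), higher (red) and lower (blue) than control. Lower genes outnumber higher ones in each table, from 9785 against 9444 in Pcz-BL-1h to 8074 against 4723 in Pcz-BL.

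The second comparison concerned the inhibitor given together with low BL, by sheet name. The Pcz-BL table held 12797 changed genes of 35343 tested (36.2%), of which 4723 were higher and 8074 lower. Median log2 fold changes were 1.43 for higher and -1.35 for lower genes, and the median over all tested genes was -0.13. Glyma06g45950 (chromosome 6, 48674323 to 48678487) rose from 0.0472 to 5.80 FPKM in the authors' deposited table (log2 fold change 6.94, q = 0.00155). Glyma16g26740 (chromosome 16, 30830562 to 30833197) rose from 0.0874 to 9.05 FPKM in the authors' deposited table (log2 fold change 6.69, q = 0.00221). Both were also higher in the authors' deposited table Pcz, at 18.2 and 5.11 FPKM. Glyma08g08761 (chromosome 8, 6264864 to 6267352) fell from 336 to 0.396 FPKM in the authors' deposited table (log2 fold change -9.73, q = 0.0135). Glyma09g02460 (chromosome 9, 1651968 to 1658743) fell from 12.9 to 0.0293 FPKM in the authors' deposited table (log2 fold change -8.78, q = 0.009999), with a large standard error of 2.08. From the normal distribution of the test statistic, 5523 genes were called. The median standard error of tested genes was 0.391, 0.493, 0.376 and 0.505 in Pcz, Pcz-BL, Pcz-BL-1h and Pcz-BL-8h. By these standard errors a call in Pcz-BL or Pcz-BL-8h would need a larger change, so the numbers of calls do not compare the extent of the responses. The deposited p-values follow the test statistic only in part: of 17974 Pcz calls, 10991 were also called from its normal distribution. The quartile of lower calls nearest to control was -0.917 in Pcz, -0.915 in Pcz-BL and -0.971 in Pcz-BL-8h. For higher calls it was 0.707, 0.952 and 0.975.

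High BL for 1 h after the inhibitor, by sheet name, was the third comparison. In Pcz-BL-1h, 19229 of 36884 tested genes (52.1%) differed from control, 9444 higher and 9785 lower. Here the higher genes moved further, with a median log2 fold change of 1.45 against -0.95. Among calls of at least 2-fold, 59.4% were higher, against 49.1% of all calls. Of the calls, 2565 higher and 514 lower ones had a mean under 1 FPKM over the 5 groups. The median standard error of tested genes was 0.766 there, against 0.376 over the table. By this standard error a call of such a gene would need a larger change, which would favour the larger median and the 2-fold share of higher genes. Glyma07g31310 (chromosome 7, 36320691 to 36322814) rose from 0.0249 to 47.5 FPKM in the authors' deposited table (log2 fold change 10.90, q = 0.00660), with a large standard error of 1.87. Glyma04g11870 (chromosome 4, 10613650 to 10616162) rose from 0.175 to 101 FPKM in the authors' deposited table (log2 fold change 9.17, q = 0.000187) and stood at 1.53 FPKM in Pcz-BL-8h. Glyma04g35130 (chromosome 4, 41476381 to 41481758) fell from 1482 to 1.40 FPKM in the authors' deposited table (log2 fold change -10.05, q = 0.000187). Glyma15g07691 (chromosome 15, 5418751 to 5421149) fell from 168 to 0.458 FPKM in the authors' deposited table (log2 fold change -8.52, q = 0.000187), while it was higher than control in the Pcz table (400 FPKM). The normal distribution of the test statistic gave 10822 calls, 5820 higher and 5002 lower, and a 2-fold minimum gave 11279.

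The fourth comparison was high BL for 8 h after the inhibitor, by sheet name. The Pcz-BL-8h table had 19563 changed genes of 34619 tested (56.5%), 8943 higher and 10620 lower. Higher and lower genes moved by similar amounts, with median log2 fold changes of 1.40 and -1.40, and the median over all tested genes was -0.10. Glyma09g01240 (chromosome 9, 761774 to 763966) rose from 0.0922 to 160 FPKM in the authors' deposited table (log2 fold change 10.77, q = 0.000496), and Glyma15g41620 (chromosome 15, 48764440 to 48767309) from 0.167 to 226 FPKM (log2 fold change 10.40, q = 0.000181). Both were also higher in the authors' deposited table Pcz-BL-1h, at 43.8 and 110 FPKM. Glyma04g35130 fell further than in Pcz-BL-1h in the authors' deposited table, from 1216 to 0.316 FPKM (log2 fold change -11.91, q = 0.000181). Glyma20g34670 (chromosome 20, 43024563 to 43029592) fell from 86.4 to 0.137 FPKM in the authors' deposited table (log2 fold change -9.30, q = 0.000181). From the normal distribution of the test statistic, 10679 genes were called.

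The direction of the calls varied with expression level. Among called genes with a mean of at least 100 FPKM over the 5 groups, 77.0% were lower in Pcz (411 of 534), 85.7% in Pcz-BL (388 of 453) and 79.2% in Pcz-BL-1h (414 of 523). In Pcz-BL-8h the share was 45.7% (224 of 490). That last share depended on how the mean was taken: with the mean over all 8 columns, which counts control 4 times and was computed first, 57.0% were lower (306 of 537), and the other 3 shares were 83.9%, 90.5% and 86.5%. Among called genes with a mean under 1 FPKM, 52.8% were higher in Pcz, 53.5% in Pcz-BL, 83.3% in Pcz-BL-1h (2565 of 3079) and 66.6% in Pcz-BL-8h. With the mean over 8 columns these shares were 63.4%, 62.99%, 88.9% and 76.1%. Restricted to 1891 such genes tested in all 4 tables, the majority was lower in each, with 17.5%, 13.8%, 40.2% and 27.4% of the calls higher. Control is the only group in all 4 tables, so this restriction favours genes with reads in control, and with them lower calls.

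Genes changed by the inhibitor were then looked up in the other tables. Over all tested genes, 22.8% were lower and 13.4% higher in Pcz-BL, 26.5% and 25.6% in Pcz-BL-1h, and 30.7% and 25.8% in Pcz-BL-8h. These shares include genes not tested in Pcz, while those below are of all Pcz calls, tested or not, so small gaps between them are not read. Among genes tested in both Pcz and Pcz-BL-1h, 1986 were higher in both, against 1648 for independent lists. There, 2245 were lower in Pcz and higher in Pcz-BL-1h, against 1994. Of the 9575 genes lower in Pcz, 59.3% were also lower in Pcz-BL and 4.07% were higher. In Pcz-BL-1h 45.1% of them were lower and 23.4% higher, and in Pcz-BL-8h 35.5% were lower and 26.8% higher. Of the 8399 genes higher in Pcz, 30.6% were higher in Pcz-BL, 23.6% in Pcz-BL-1h and 20.9% in Pcz-BL-8h, while 3.57%, 19.4% and 33.5% were lower there. By the z test of the difference, 9.70% of the 9575 Pcz-lower genes lay closer to control or beyond it in Pcz-BL, 42.6% in Pcz-BL-1h and 44.3% in Pcz-BL-8h. For the 8399 Pcz-higher genes these shares were 6.06%, 30.3% and 39.6%. Of the genes with a z test in each case, at most 3.38% moved further from control. Selecting genes by their call in Pcz favours movement towards control. By the standard errors a call in Pcz-BL or Pcz-BL-8h would need a larger change than one in Pcz, so a missing call there does not show a return to control.

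**Figure D2:**
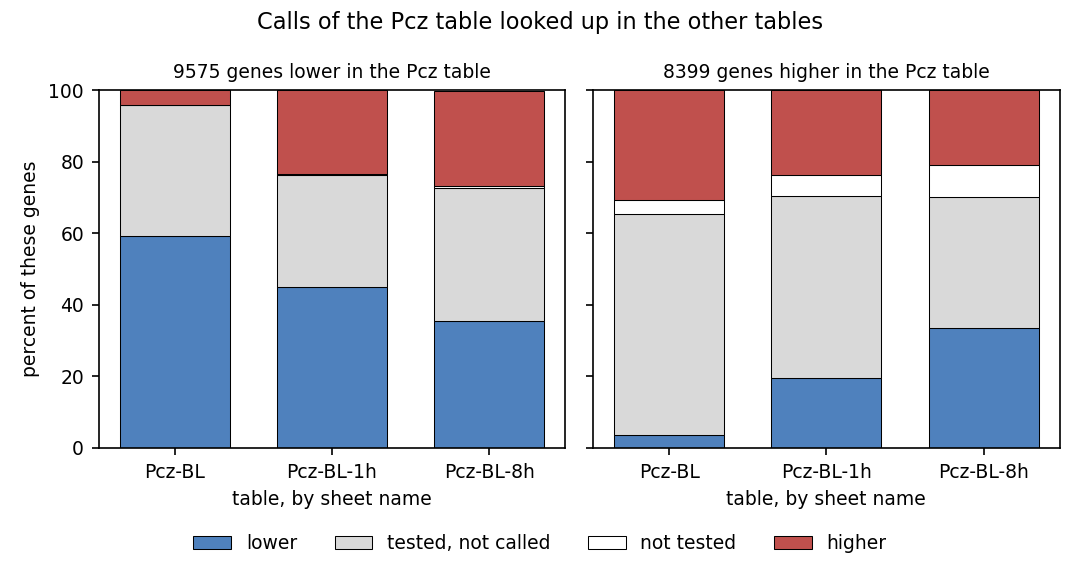
Genes lower (left) and higher (right) than control in the Pcz table, looked up in the other 3 tables (horizontal axis). Bars show the percent of these genes (vertical axis) called lower (blue), tested and not called (grey), not tested (white) or called higher (red); 59.3% of the Pcz-lower genes were lower in Pcz-BL and 35.5% in Pcz-BL-8h.

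The 4 tables formed 2 pairs. Pcz and Pcz-BL shared 8942 called genes, 92.3% of them in the same direction, with 5678 lower in both (2290 for independent lists, odds ratio 13.8, 95% interval 13.0 to 14.7) and 2574 higher in both (1003, odds ratio 7.13, 6.65 to 7.64). Pcz-BL-1h and Pcz-BL-8h shared 11670 called genes, 90.7% in the same direction, with 4721 higher in both (1936, odds ratio 9.31, 8.80 to 9.86) and 5861 lower in both (3040, odds ratio 6.20, 5.88 to 6.52). Across the pairs, calls of Pcz and Pcz-BL-8h went the same way in 5152 genes and opposite ways in 5377. Their odds ratios were 0.94 for higher in both (95% interval 0.89 to 1.00) and 1.21 for lower in both. For opposite calls they were 1.26 (higher in Pcz) and 1.28 (lower in Pcz). Pcz and Pcz-BL-1h shared a direction in 6301 genes, with odds ratios of 1.39 for higher and 2.70 for lower in both. They differed in 3878, with odds ratios of 0.54 (higher in Pcz) and 1.24 (lower in Pcz). Pcz-BL and Pcz-BL-1h shared a direction in 5560 genes, with odds ratios of 3.33 for higher and 2.85 for lower in both, and differed in 2686. Pcz-BL and Pcz-BL-8h shared a direction in 4022 and differed in 3612. The controls could not be split, so part of the excess may come from the shared control libraries. The intervals treat genes as independent, which they are not, and do not measure the spread between libraries.

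Fold changes gave the same pairs across genes, which are not independent replicates. Pearson's r was 0.71 between Pcz and Pcz-BL (33121 genes, Spearman's rho 0.64, covariance 0.683 against 0.0836 simulated from a shared control) and 0.65 between Pcz-BL-1h and Pcz-BL-8h (34054 genes, rho 0.62, covariance 0.644 against 0.0796). It was 0.21 between Pcz and Pcz-BL-1h (covariance 0.199 against 0.0644) and 0.04 between Pcz and Pcz-BL-8h (0.0461 against 0.0851). Between Pcz-BL and Pcz-BL-1h r was 0.23 (covariance 0.176 against 0.0824), and between Pcz-BL and Pcz-BL-8h it was 0.03 (0.0258 against 0.101). Simulated correlations lay near 0.50 in each pair, so the covariances are the values to compare. In all, 6 pairs were computed.

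**Figure D3:**
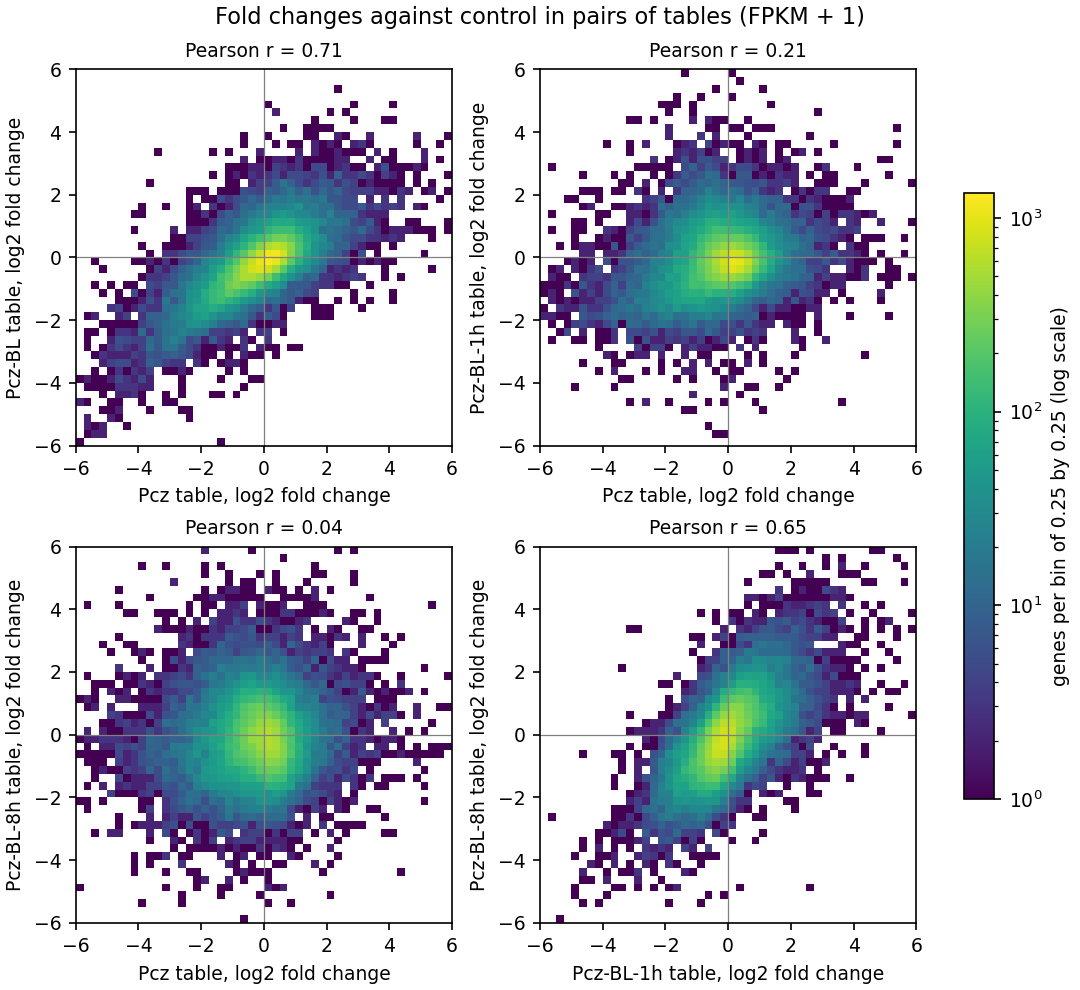
Log2 fold changes against control, on the log2(FPKM + 1) scale, of genes tested in both tables, for 4 pairs of tables (each axis 1 table, limited to -6 to 6), with colour for the number of genes per bin on a log scale. The Pcz and Pcz-BL tables (r = 0.71) and the Pcz-BL-1h and Pcz-BL-8h tables (r = 0.65) lie along a diagonal, the Pcz and Pcz-BL-8h tables (r = 0.04) do not.

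Of 32174 genes tested in all 4 tables, 27640 (85.9%) were called in at least 1 and 4030 in all 4. There were 1640 genes lower in all 4 (232 for independent lists) and 536 higher in all 4 (41.5). Another 818 were lower in Pcz and Pcz-BL and higher in both other tables (111), and 1698 were lower in Pcz-BL-1h and Pcz-BL-8h and called in neither of the others (957). The counts for independent lists take no account of the shared control libraries, which alone favour calls in the same direction.

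Levels were also set against the inhibitor alone, across tables that were normalised separately and without a p-value. The control level of the Pcz-BL-8h table was 0.829 times that of Pcz-BL, and the median log2 ratio of Pcz-BL-8h was -0.28 to Pcz and -0.26 to Pcz-BL-1h, so splits with that table carry this shift. The control column of the Pcz table differed gene by gene from that of Pcz-BL, with an SD of the log2 ratio of 0.188 and 339 genes beyond 1.5-fold. All contrasts with Pcz carry this difference, which a single scaling does not remove. Pcz-BL differed from Pcz by at least 2-fold in 6062 of 30949 genes, 3201 higher and 2861 lower; scaled to the same median the split was 3847 higher and 2269 lower. Pcz-BL-1h differed in 12374 of 34404 genes, 7653 higher and 4721 lower, and 8930 higher and 3539 lower when scaled to the same median. Pcz-BL-8h differed in 15915 of 32477 genes, 6586 higher and 9329 lower, and scaling to the same median turned this split to 8328 higher and 7466 lower. Differences of the fold changes within each table gave 2867 higher and 2347 lower for Pcz-BL, 7479 and 4628 for Pcz-BL-1h, and 7814 and 7502 for Pcz-BL-8h. For Pcz-BL-1h the median log2 ratio was only -0.03 before scaling, while the scaling ratio was 0.857. Its scaled split is therefore not centred on the typical gene. By the z test, which takes the errors of the 2 tables as independent and so misses differences, 1707, 8313 and 11011 genes differed from Pcz.

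From Pcz-BL-1h to Pcz-BL-8h, levels differed by at least 2-fold in 8333 of 33404 genes, 2039 higher and 6294 lower, and differences of the fold changes within each table gave 3266 higher and 4414 lower. The z test called 2545 genes, 876 higher and 1669 lower. Over genes with finite fold changes, the 4654 called higher in both tables (of 4721) had a median log2 fold change of 1.44 in Pcz-BL-1h and 1.78 in Pcz-BL-8h, and the 5804 called lower in both (of 5861) -1.05 and -1.50. By the standard errors a call in Pcz-BL-8h would need a larger change (median 0.505 against 0.376), which would favour these larger medians. Chosen by their call in Pcz-BL-1h alone, higher genes had medians of 1.45 and 1.16 and lower genes -0.95 and -0.93, a choice that favours Pcz-BL-1h. No change of size with time is read from either.

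The authors' short lists held 3448, 2478, 2915 and 3981 genes for Pcz, Pcz-BL, Pcz-BL-1h and Pcz-BL-8h. Each was the set of genes with the smallest possible p of 5e-05 and a finite absolute log2 fold change above 2. Lower genes prevailed in the lists of Pcz (2355 against 1093), Pcz-BL (1530 against 948) and Pcz-BL-8h (2122 against 1859), and higher genes in that of Pcz-BL-1h (2147 against 768). Of 9084 genes in any list, 82 were in all 4, of which 26 were higher and 35 lower throughout.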

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

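The z test of the difference between fold changes and both comparisons of covariances with simulated shared controls, and the test of a uniform background as now given, were chosen only after the results were seen; the other tests below were written before their values were computed, on patterns already noticed. Genes called in opposite directions in 2 tables, with a difference by the z test, numbered 470 between Pcz-BL and Pcz, 3457 between Pcz-BL-1h and Pcz, 4998 between Pcz-BL-8h and Pcz, and 701 between Pcz-BL-8h and Pcz-BL-1h.

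The grouping of the tables into Pcz with Pcz-BL and Pcz-BL-1h with Pcz-BL-8h was weighed first. Shared control libraries are argued against, since the lower of the 2 covariances within pairs was 8.09 times the simulated one. A few extreme genes do not carry it alone: without genes at an absolute log2 fold change of 3 or more, the lower covariance within pairs was still 5.004 times the simulated one. This replaced a bound on the correlation, which was 0.603 without those genes, because a shared control alone gave 0.504. By sheet name the pairs separate the groups without high BL from those with it, and a lasting response to high BL is a candidate explanation. Such a response cannot be told apart from an effect of the addition itself, as no group was given a mock addition after Pcz. By column header one pair would instead join Pcz with high BL for 1 h and the other high BL for 8 h with the remaining group, so the hypothesis rests on the sheet names, and library or harvest batches stay open, as the labels give none and their library codes, of unstated meaning, are 5 to 10 in one pair and 11 to 15 and 2 in the other.

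Genes of low mean FPKM were called mostly higher in Pcz-BL-1h (83.3% of 3079 calls). Of the 10493 genes listed at 0 in control, 30.03% were above 0 in Pcz-BL-1h, against 20.7% in Pcz-BL and 17.7% in Pcz-BL-8h. In the Pcz table, 15.7% of the 10507 genes listed at 0 in its own control column were above 0. The first bound, that under 50% above 0 argues against a uniform background of reads, was dropped because a thin background also leaves genes at 0. Of 3570 genes at 0 in control and seen in another treated column, 9.38% reached 0.629 FPKM, by which at least 75% of the low genes called higher rose. Those called genes were picked for a large rise and the 3570 were not, so a low share could arise with or without a background. This test can therefore not decide, and a uniform background stays open as the whole cause or as part of it. Which genes had enough reads to be tested was also weighed. Among low genes tested in all 4 tables, the share of calls that were higher was 40.2%, just inside the 40 to 60% written beforehand for this explanation. That restriction leaves out any gene expressed in Pcz-BL-1h alone. It also favours genes with reads in control, the only group in all 4 tables, and with them lower calls. The test can therefore not decide whether the choice of tested genes contributes. The share was still above the 17.5%, 13.8% and 27.4% of Pcz, Pcz-BL and Pcz-BL-8h.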

How the results depend on the processing

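The alternatives named here as the normal p-value, the 2-fold share of higher calls, the binning, the within-table difference, the z test, recentring, overlapping models and another control were chosen after seeing the data. No paired analysis was possible because the tables hold 1 pooled value per group; for the same reason no library was left out and no count model was run, and the alternatives of the fixed gene lists were not run because no ID could be matched. Of the values under alternatives, 71 stayed within the tolerance (1.5 times for a count, 10 percentage points for a share, the 95% jackknife interval for a correlation), 32 moved beyond it and 4 shares turned to the other side of 50%. Of the 71, 9 could not have moved or tested the sign alone (recentring, the q recomputed over each table, the other control), which leaves at most 62. Those 62 still hold the counts without overlapping gene models, which could not pass the tolerance either. Only 3548 genes overlap another, too few to change any count of calls by 1.5 times. Normal p-values gave 11480, 5523, 10822 and 10679 calls for Pcz, Pcz-BL, Pcz-BL-1h and Pcz-BL-8h. A 2-fold minimum gave 11160 for Pcz and 11279 for Pcz-BL-1h, of which 59.4% were higher, a turn from under 50%. The share lower at 100 FPKM or more in Pcz-BL-8h turned to 57.0% with the mean of 8 columns, and that under 1 FPKM in Pcz became 36.6%. Pearson's r moved to 0.72, 0.72 and 0.72 (0.722, 0.716 and 0.715) for Pcz and Pcz-BL with pseudocounts 0.1 and 5 and the FPKM filter, to 0.165 and 0.3001 for Pcz and Pcz-BL-1h with pseudocounts 0.1 and 5, to 0.193 and 0.318 for Pcz-BL and Pcz-BL-1h, and to 0.0802 and 0.0666 for Pcz and for Pcz-BL with Pcz-BL-8h at pseudocount 5. For Pcz-BL-1h and Pcz-BL-8h it was 0.675 with pseudocount 0.1 and 0.672 with the filter. At a q of 0.01, 2678 calls of Pcz-BL and Pcz-BL-8h shared a direction. With pseudocount 5, 2461, 5138 and 7591 genes differed at least 2-fold from Pcz in Pcz-BL, Pcz-BL-1h and Pcz-BL-8h, and 2468 between Pcz-BL-8h and Pcz-BL-1h. The z test called 1707 for Pcz-BL against Pcz and 2545 for Pcz-BL-8h against Pcz-BL-1h. The share higher became 62.9% for Pcz-BL against Pcz when scaled to the same median, turned to 52.7% (scaled) and 51.02% (within tables) for Pcz-BL-8h against Pcz, and became 42.5% within tables for Pcz-BL-8h against Pcz-BL-1h. A higher pseudocount shrinks folds of low genes by construction; otherwise the cause was not tested. Recentring on the median turned the sign of no called gene, so it says nothing on stability. With the control of the Pcz-BL table, 17772 of 17783 Pcz calls kept their direction. The z test recovered few planted differences of 2 on the log2 scale, and unknown depth limits what can be said of low genes.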

Other observations

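No test below was chosen after its result was seen, except the summary of the control columns by a single scaling factor. In the order of tested genes, with untested ones passed over, genes changed in the same direction lay next to each other more often than by chance. Same-direction neighbours numbered 5531, 3138, 5729 and 6354 in Pcz, Pcz-BL, Pcz-BL-1h and Pcz-BL-8h, against means of 4800, 2466, 4999 and 5551 over 1000 permutations. The longest runs were 12 genes lower in Pcz on chromosome 2 (2727037 to 2880148), 9 of which were also lower in Pcz-BL, 9 lower in Pcz-BL-1h and 6 higher in Pcz-BL-8h, and 12 genes higher in Pcz-BL on chromosome 16 (32337759 to 32518687), with a median log2 fold change of 2.43. These 2 runs were longer than any in 100 permutations (at most 11 and 10 genes), while the longest runs of Pcz-BL-1h (9) and Pcz-BL-8h (11) were not (11 and 13). Runs of 6 or more genes numbered 53, 19, 46 and 66, against means of 19.1, 4.31, 17.3 and 27.3 over 100 permutations.

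Chance placement is argued against, as the count lay above every permutation in 4 of 4 tables. Reads shared between overlapping gene models do not account for the excess, since at least 91.4% of the relative excess (observed over permuted count, minus 1) and 90.9% of the excess in pairs was left without those models. Whether next-door gene copies, sharing reads or promoters, may be the cause cannot be told apart from regional control: the excess 10 places apart was 5.20 to 11.2% of that between next neighbours, and no sequences were used here to find copies.

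The control columns differed between tables. Against the Pcz-BL table, the log2 ratio of control FPKM had an SD of 0.188 in the Pcz table (29428 genes), with 339 genes beyond 1.5-fold, and 0.174 at 50 FPKM or more. For Pcz-BL-1h and Pcz-BL-8h the SD was 0.00121 and 0.00709 around median ratios of 1.003 and 0.829, so those columns differed from that of Pcz-BL by little more than a single factor. For the Pcz table, a single scaling factor needed an SD of at most 0.02, noise of low genes an SD of at most 0.02 at 50 FPKM or more, and locus length an absolute Spearman's rho of at least 0.3 at 50 FPKM or more, where it was -0.0420. None of these 3 conditions was met. The low-FPKM pattern of Pcz-BL-1h was taken up for weighing in place of this one after these values were seen. An unlabelled column beside the Pcz table held 59 IDs, all among the 61 genes of the same direction in all 4 short lists. The numeric library codes in the labels, whose meaning is not given, mostly follow the groups, with code 2 apart from the rest of its group: control has 1, 4 and 3, Pcz 6, 5 and 8, Pcz with low BL 7, 10 and 9, Pcz-BL-1h 14, 11 and 12, and Pcz-BL-8h 13, 15 and 2.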
